A study of Mus musculus with 38 samples.

How the data were processed

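RNA-seq was made from intestinal tissue of wild-type C57BL6/J mice that had been made vitamin D deficient. Per the labels' protocols, the mice received an intraperitoneal injection of 1,25(OH)2D3, the hormonal form of vitamin D, at 10 ng per g of body weight, or 0.1 ml of its propylene glycol and ethanol vehicle, and were killed after 4 h. Villi and crypts of the proximal small intestine were loosened with EDTA and parted on a filter, and colon epithelium was scraped off the muscle with a glass slide, per the labels' protocols. The 38 libraries fell into 6 groups taken from the sample titles: 6 vehicle and 7 vitamin D libraries of villi, 6 and 6 of crypts, and 6 and 7 of colon. The number of mice behind a library is not given in the sources used here, so p-values measure only the spread between these samples. The labels call the mice pooled males and females, whereas Xist and Ddx3y, checked in each library, gave 24 libraries with the female and 14 with the male pattern.

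For each tissue the authors deposited a table of FPKM, fragment counts scaled by transcript length and library size, with 21441 genes and a column per library, per the file headers. The authors also deposited tables of their own comparisons with a mean level, a log2 fold change, its standard error, a p-value and an adjusted p-value per gene, per the file headers. Per the submitters' processing notes, kallisto 0.45.0, DESeq 1.28.1 and DESeq2 were among the tools and mm9 was the genome build; which tool made which column is not given in the sources used here, so no genomic coordinates are reported. The 3 FPKM tables were treated as normalised separately: within a tissue the authors' deposited log2 fold changes and those of the mean FPKM had a median offset of 0.00 for villi, crypts and colon, whereas between tissues the offset was 0.49 for crypts against villi, 0.70 for colon against villi and 0.08 for colon against crypts. Tests were therefore made within a tissue's table, and levels set side by side across tissues come from separately normalised tables. The depth behind the FPKM was read from the steps between low values: a library held 13.8 M to 17.5 M reads (median 15.8 M), with 78.1% to 91.5% of the values worth under 30 reads within 0.05 of a whole number. These recovered numbers served only to give the depth and to compare pairs of libraries, and no count model was run on them. No pair of libraries of a group agreed within sampling noise (lowest chi-square per degree of freedom 12.7), so none was taken as a repeated run of another. Each library counted as 1 replicate, though this check cannot tell whether libraries came from separate mice.

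Genes with an FPKM of 1 or more in at least 6 libraries of the tissue were tested on log2(FPKM + 0.5) with limma 3.58.1 (lmFit and eBayes with trend) in R 4.3.3, vitamin D against vehicle, with no covariate. The p-values were adjusted by Benjamini and Hochberg's method over all genes tested in the tissue, at a threshold of 0.05, and all adjusted p-values of genes are from limma. Gene lists, 30 in number with 439 distinct genes, were tested with limma's camera at a preset inter-gene correlation of 0.01 where at least 3 members passed the filter; 418 of the genes matched by symbol, 11 by an older symbol, and 10 were not analysed here. Each list's members were counted by the test over all genes and by the same p-values adjusted over the list alone. The list of sex-linked genes served as a check and was not tested as a set. Differences of the response between tissues were tested as contrasts of contrasts in 1 limma fit over all 38 libraries. The overlap of called genes was tested with Fisher's exact test, two-sided, on genes tested in both tissues. Comparisons of tissue with tissue among vitamin D treated libraries come from the authors' deposited tables at their adjusted p-value of 0.05.

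The samples, tests, gene lists and rule for named genes were fixed before the data were examined. By that rule, each vitamin D comparison names Vdr, Cyp24a1, Cyp27b1, Trpv6, S100g and Atp2b1 whatever their test, the 10 largest rises and 6 largest falls among called genes with a mean FPKM of 2 or more in the higher group and an ordinary gene symbol, and up to 3 called members of each list by smallest p. A difference of response names the 6 genes of smallest p per pair of tissues together with the first 6 genes above. Tissue comparisons name up to 2 members of each list with the largest change in each direction and the 5 largest changes in each direction among genes above the median of the authors' mean level; of these genes a selection is printed. Genes named outside this rule are said to have been chosen after their values were seen.

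Libraries of a tissue share replicate numbers across vehicle and vitamin D in their titles. The table columns carry other numbers for some number-prefixed libraries, and by these vehicle replicate 6 pairs with vitamin D replicate 7 in villi, and vehicle replicates 5 and 6 with vitamin D replicates 6 and 7 in colon. The titles pair a male with a female library at number 6 in villi and 5 in colon, the columns join libraries of the same sex throughout, and the blocks below follow the titles unless said otherwise. Deviations from the group means correlated at 0.102 to 0.465 between same-numbered libraries of villi and at 0.119 to 0.545 in crypts, over 0.1 in 6 of 6 pairs each. In each of these tissues only 3 of 6 vehicle libraries correlated best with their own number. By the cut-off of 0.1 the numbers were taken to pair these libraries, though the pairing is weak. Same-numbered libraries of these tissues also shared sex pattern and name style, except at number 6 in villi. The correlations and the block therefore cannot part pairing from sex or a possible batch. Values with the replicate number as a block stand beside a result where they change it. The library names given in the sample descriptions have 3 styles, plain in 24, with a hyphen in 6 and with a number prefix in 8, whose meaning is not given in the sources used here; they were treated as possible batches. The table columns themselves hold no hyphens. Libraries with a number prefix were all male and those with a hyphen all female, and these styles allow fits of 2 against 2 libraries, with a prefix in villi and colon and with a hyphen in crypts.

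The alternatives were pseudocounts of 0.1 and 1, no filter or a mean FPKM of 5 or more, median-scaled libraries, array weights, robust shrinkage, name style as a covariate, plain-named libraries only, the replicate block, a log2 fold change of at least 1, an estimated inter-gene correlation and the authors' deposited tables. Sex as a covariate, leaving out each library in turn, the plain-named libraries alone for gene lists and for differences between tissues, fits within the other name styles and the block by column names were added after seeing the data. The scripts were tested on simulated data made from the FPKM of these genes, with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were drawn from those with a mean FPKM of 5 or more, and the noise was independent between genes and libraries. The shares recovered below thus do not cover lower genes, and the shares of false calls do not allow for batches, pairs or correlated genes. In villi 90% of the 2-fold and 99% of the 4-fold changes were recovered over 9673 genes, with 3.57% of calls false. The figures were 88%, 100% and 2.59% over 10702 genes in crypts, and 88%, 99.0% and 5.10% over 11631 genes in colon. For differences between tissues, 74% of 2-fold and 96% of 4-fold changes were recovered for villi and crypts (6.59% of calls false, 10919 genes). The corresponding values were 76%, 98% and 7.45% for villi and colon over 11933 genes, and 76%, 94% and 10.5% for crypts and colon over 12025 genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The results of 2 genes of the lists are not reported here.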

Results

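Gene expression was measured by RNA-seq in villi, crypts and colon of vitamin D deficient mice, 4 h after an injection of 1,25(OH)2D3 or vehicle. There were 6 vehicle and 7 vitamin D libraries of villi, 6 and 6 of crypts, and 6 and 7 of colon, with 13.8 M to 17.5 M reads each. Values are FPKM with the SD over libraries, and fold changes are on log2(FPKM + 0.5) with their standard error, which understates the change of low genes. The comparisons address which intestinal genes respond to the hormone, and whether the response differs between villus, crypt and colon.

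In villi, Cyp24a1, the hydroxylase that inactivates 1,25(OH)2D3, rose from 10.98 ± 25.1 FPKM (SD, n = 6) to 3378 ± 877 (n = 7). Its log2 fold change was 10.53 ± 0.83 (adjusted p = 1.5e-05), with 7 of 7 vitamin D libraries above every vehicle library. The vehicle mean rested on replicate 6 at 62.2 FPKM. S100g, the cytosolic calcium buffer calbindin-D9k, rose from 708 ± 259 to 1762 ± 528 FPKM (1.36 ± 0.27, adjusted p = 0.0141). That call was lost with the replicate number as a block (adjusted p = 0.0725, but 0.0418 with the pairs of the column names) and in the plain-named libraries alone (0.0520). Atp2b1, the basolateral calcium pump, rose from 43.0 ± 3.37 to 111 ± 23.0 FPKM (1.33 ± 0.12, adjusted p = 3.4e-05). Trpv6, the apical calcium channel, stood at 0.602 ± 0.558 and 1.87 ± 1.06 FPKM (1.08 ± 0.37, adjusted p = 0.200), with 5 of 7 vitamin D libraries above all vehicle libraries and 1 below them all. It passed with name style as a covariate (adjusted p = 0.0171). The receptor gene Vdr stood at 138 ± 32.1 and 161 ± 35.9 FPKM (0.22 ± 0.17, adjusted p = 0.675). Cyp27b1, which makes the hormone, lay below the filter in each tissue.

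Among 9706 genes tested in villi, limma called 240, of which 211 rose and 29 fell, and 341 with the replicate number as a block (288 higher, 53 lower). The fallen count was 15 to 28 without 1 library, lowest without vehicle replicate 1 or vitamin D replicate 2. After Cyp24a1, the largest rises were those of the matrix protein gene Spon2 (log2 fold change 3.08 ± 0.32, adjusted p = 0.000151) and the glutathione transferase gene Gstm3 (203 ± 80.8 to 1526 ± 642 FPKM, 2.90 ± 0.31). The sugar-phosphate carrier gene Slc37a2 rose from 15.0 ± 6.87 to 97.3 ± 17.1 FPKM (2.75 ± 0.23, adjusted p = 2.9e-05). Gstm1 rose by 2.29 ± 0.32, and the claudin gene Cldn2, whose product forms a paracellular cation pore, by 1.99 ± 0.37. Pdlim2 rose by 1.83 ± 0.21 and the desmosomal gene Pkp1 by 1.80 ± 0.37. Shmt1, of one-carbon metabolism, rose from 5.37 to 20.5 FPKM, and the receptor phosphatase gene Ptprj from 5.74 ± 0.599 to 21.7 ± 4.17 FPKM.

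The metallothionein gene Mt2 fell in villi from 83.3 ± 42.6 to 22.7 ± 12.8 FPKM (-1.93 ± 0.43, adjusted p = 0.0263), and the spindle gene Nusap1 from 7.78 to 2.52 FPKM (-1.48 ± 0.33, adjusted p = 0.0285). These calls were lost without any 1 of 5 and 7 of the 13 libraries, with adjusted p up to 0.0626 and 0.0671, each highest without vehicle replicate 1. Without a filter on low genes their adjusted p was 0.0546 and 0.0595. Adh4 fell by 0.98 (adjusted p = 0.0201, and 0.0516 without vehicle replicate 5). The apoptosis gene Bid fell by 0.89 (adjusted p = 0.0201, and 0.0514 without vehicle replicate 1). Arl4d fell by 0.87, and the tubulin gene Tubb2a by 0.86 (adjusted p = 0.0136, and 0.0582 with the replicate number as a block or 0.0166 with the pairs of the column names). The authors' deposited table called 436 genes in villi, 350 higher and 86 lower, with 239 of the 240. Within the plain-named libraries, 4 against 4, 97 genes passed (93 higher, 4 lower), 90 of them among the 240. Pkp1, Mt2, Nusap1, Adh4, Bid and Arl4d did not pass there (adjusted p of 0.0888 to 0.287).

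**Figure D1:**
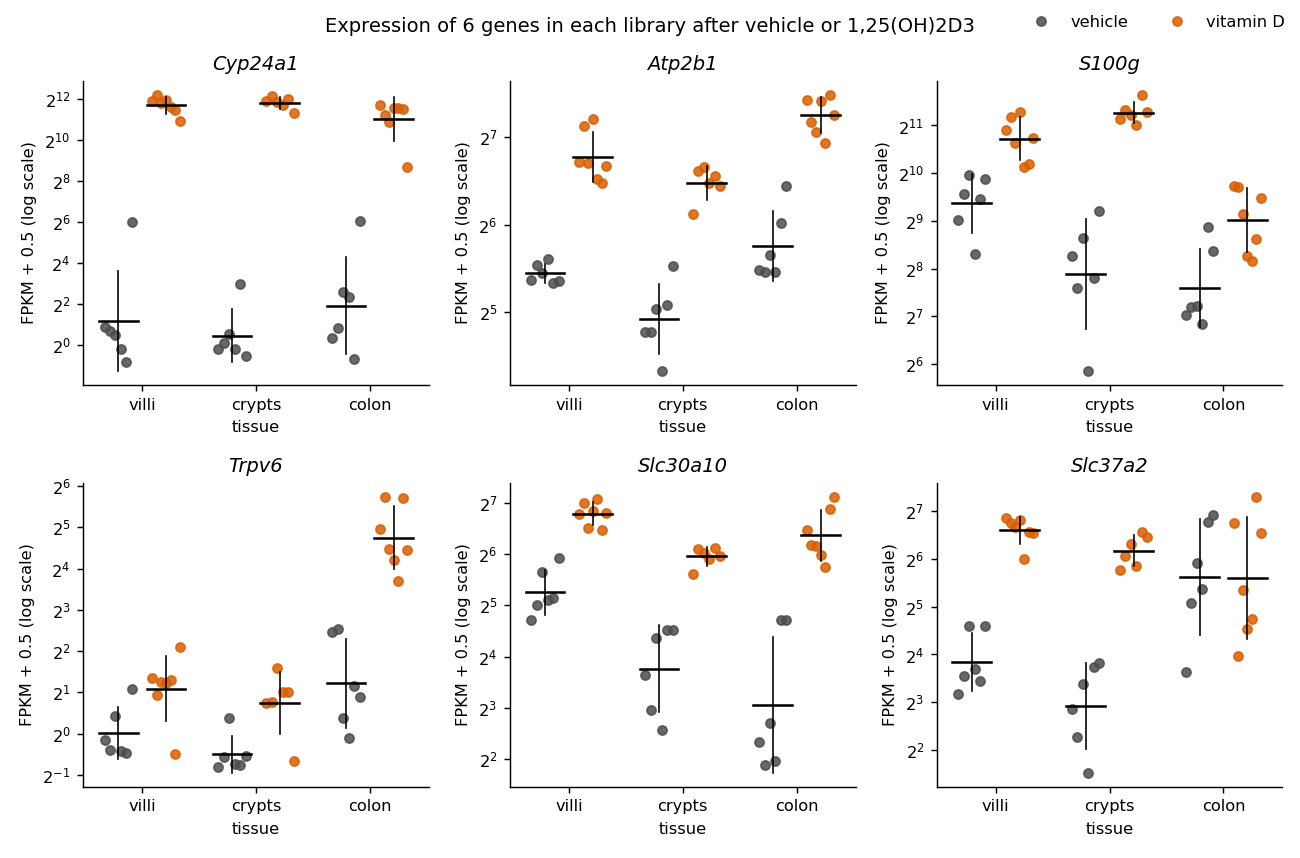
FPKM + 0.5 on a log axis of 6 genes in each library (points) of villi, crypts and colon after vehicle or 1,25(OH)2D3, with the mean (thick line) and SD (thin line) of the log2 values. Cyp24a1 lay at 403 FPKM or more in every vitamin D library and at 64.7 or less in every vehicle library, while Slc37a2 separated the groups in villi and crypts and overlapped in colon.

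Calcium absorption was the list of 24 that passed in villi (camera, higher, adjusted p = 0.000588; adjusted p = 0.554 with an estimated correlation). Of its 7 measured members, S100g, Atp2b1 and Cldn2 rose over all genes and 4 rose when adjusted over the list alone, with a median log2 fold change of 1.08. Among 20 genes of zinc, manganese and iron handling, 4 rose and 2 fell, or 6 and 3 adjusted over the list alone. The list did not pass (median -0.01, mean 0.06, test higher, adjusted p = 0.248). Those that rose were the manganese exporter gene Slc30a10 (39.3 to 111 FPKM, 1.53 ± 0.18), the zinc transporter genes Slc30a1 (1.37 ± 0.18) and Slc30a5 (0.43 ± 0.07), and the importer gene Slc39a8 (1.11 ± 0.19). Mt2 and the iron importer gene Slc11a2 (47.8 ± 18.1 to 28.0 ± 3.73 FPKM) fell. Slc39a8, Slc11a2 and Slc34a2 were chosen here after their values were seen. In the phosphate and magnesium list Cnnm2 (5.14 to 12.1 FPKM, 1.15 ± 0.17) was the called gene of 9, with 2 risen adjusted over the list alone. The phosphate carrier gene Slc34a2 stood at 6.63 ± 8.38 and 31.3 ± 20.2 FPKM (adjusted p = 0.0611). Gstm1 was the called gene of 23 xenobiotic genes, with 3 risen adjusted over the list alone. Both lists had an adjusted p of 0.0983. The phosphate list passed with name style as a covariate (0.0235; adjusted p = 0.229 with an estimated correlation). With the replicate number as a block, the xenobiotic list (higher, 0.0087) and the cell cycle list (lower, 0.0491, against 0.143 without the block and 0.252 with the pairs of the column names) passed, each at an adjusted p of 0.953 with an estimated correlation.

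Hopx (1.03 ± 0.17, adjusted p = 0.00431) was the called gene of 11 stem cell genes in villi, a list with an adjusted p of 0.370. Cholesterol synthesis genes did not pass as a list in villi (adjusted p = 0.764), with 1 of 18 called, higher. Cyp24a1 was the called gene of 12 genes of vitamin D receptor and metabolism, a list with an adjusted p of 0.105, and 0.0445 with name style as a covariate (adjusted p = 0.991 with an estimated correlation). The 8 measured glucocorticoid targets had negative fold changes (median -0.41, adjusted p = 0.102, and 0.0454 within the plain-named libraries, where it was 0.961 with an estimated correlation). Limma called 0 of them, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 in the authors' deposited table. The kinase gene Sgk1, of that list and chosen after its values were seen, stood at 190 ± 207 and 60.9 ± 39.9 FPKM. Of 62 markers of Paneth cells (13), absorptive enterocytes (20), goblet (11), enteroendocrine (12) and tuft cells (6), limma called 0, also adjusted over the list alone. Of these, 3 enterocyte genes had an unadjusted p under 0.05, and the authors' deposited table called 1. The adjusted p of these lists was 0.483, 0.248, 0.935, 0.899 and 0.432. Median, mean and test also differed in sign for fatty acid oxidation and PPAR targets (-0.01, -0.02, higher) and for lymphocytes and plasma cells (-0.01, 0.02, higher), both with an adjusted p of 0.972. Other splits of the villus libraries into groups of these sizes gave up to 11 called lists.

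In crypts, Cyp24a1 rose from 1.62 ± 2.82 FPKM (SD, n = 6) to 3625 ± 670 (n = 6; log2 fold change 11.37 ± 0.48, adjusted p = 6.5e-08), with vehicle replicate 5 at 7.35 FPKM. S100g rose from 294 ± 184 to 2491 ± 387 FPKM (3.38 ± 0.43, adjusted p = 0.000911) and Atp2b1 from 30.7 ± 8.74 to 89.1 ± 11.2 FPKM (1.56 ± 0.17, adjusted p = 0.000246), each in 6 of 6 libraries. Trpv6 lay below the filter at 0.239 and 1.34 FPKM. The authors' deposited table gave it a log2 fold change of 2.48 at an adjusted p of 0.00886. Vdr stood at 195 and 248 FPKM (0.34 ± 0.17, adjusted p = 0.381). Prelp, a leucine-rich-repeat protein of the matrix, rose from 9.18 ± 3.72 to 126 ± 41.2 FPKM (3.73 ± 0.30, adjusted p = 3.0e-05) and Slc37a2 from 8.29 ± 4.55 to 72.8 ± 16.2 FPKM (3.23 ± 0.35).

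Limma called 157 of 10733 genes in crypts, 121 higher and 36 lower, and 444 with the replicate number as a block (249 higher, 195 lower). Wfdc16 rose by 3.06 ± 0.22 (adjusted p = 8.5e-06), the B-cell receptor gene Cd79b by 2.41 ± 0.35, Slc30a10 by 2.19 ± 0.32 and the cytoskeletal gene Shroom1 by 2.03 ± 0.36. The growth factor gene Pdgfa rose from 0.669 to 4.75 FPKM (adjusted p = 0.00568), whereas the authors' deposited table gave it an adjusted p of 0.169. Gstm3 rose by 2.35 ± 0.52 (adjusted p = 0.0413), with an SD of 1133 FPKM around a vitamin D mean of 1160. Vav3, an exchange factor gene, fell from 2.43 to 0.752 FPKM (-1.20 ± 0.17, adjusted p = 0.0026). Lrat, whose product makes retinol esters, fell from 6.61 to 2.88 FPKM (-1.08 ± 0.18, adjusted p = 0.00869). Adh4 (-1.48 ± 0.31, adjusted p = 0.0313), Arl4d (-1.12 ± 0.24, 0.0403), Fam73b (-1.05 ± 0.22, 0.0278) and Cyp2u1 (-0.99 ± 0.22, 0.0413) also fell. The calls of Gstm3, Adh4, Arl4d, Fam73b and Cyp2u1 were lost without any 1 of 8 to 10 of the 12 libraries, with adjusted p up to 0.111, and except for Fam73b also within the plain-named libraries.

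The count of called genes in crypts varied with the libraries and terms of the fit. It was 1065 without vehicle replicate 4, with all 157 among them. It was 391 with name style as a covariate and 272 with sex as a covariate. Within the plain-named libraries, 4 against 4, limma called 84 genes (80 higher, 4 lower), 73 of them among the 157. The authors' deposited table called 550 genes, 308 higher and 242 lower.

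Of the 25 lists tested in crypts, 6 passed camera with the preset correlation and 0 with an estimated one. Among 6 calcium absorption genes S100g, Atp2b1 and Cldn2 (118 to 336 FPKM, 1.43 ± 0.25) rose, 3 also adjusted over the list alone. The list was higher at an adjusted p of 0.000659 (adjusted p = 0.545 with an estimated correlation). Of 22 cell cycle genes 21 had a positive fold change, with a median of 0.24 (adjusted p = 0.000659; adjusted p = 0.980 with an estimated correlation). Limma called 0 of them over all genes or adjusted over the list alone, 7 had an unadjusted p under 0.05, and the authors' deposited table called 0. The cyclin gene Ccnd1, chosen after its values were seen, stood at 29.8 ± 9.51 and 42.2 ± 6.95 FPKM. The 13 Paneth cell genes had positive fold changes (median 0.28), such as the defensin gene Defa20, also chosen after its values were seen, at 348 ± 84.7 and 469 ± 128 FPKM. Of these limma called 0, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 in the authors' deposited table. The Paneth list passed at an adjusted p of 0.0396 (adjusted p = 0.980 with an estimated correlation). It did not pass with the replicate number as a block (0.0743), with name style as a covariate (0.0547), without vehicle replicate 6 (0.252) or within the plain-named libraries (0.557).

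Absorptive enterocyte genes had negative fold changes in crypts in 19 of 20, with a median of -0.50, and the brush border disaccharidase gene Sis, chosen after its values were seen, stood at 1706 ± 476 and 945 ± 170 FPKM. The list passed at an adjusted p of 0.0102 (adjusted p = 0.980 with an estimated correlation), but not without vehicle replicate 6 (0.192) or within the plain-named libraries (0.222). Fatty acid oxidation and PPAR targets had 14 negative fold changes of 15, with a median of -0.48. That list passed at an adjusted p of 0.0123 (adjusted p = 0.980 with an estimated correlation; 0.0575 without vehicle replicate 6). In both lists limma called 0 genes, also adjusted over the list alone. At an unadjusted p under 0.05 there were 2 and 3, and the authors' deposited table called 1 and 0. The glucocorticoid targets were lower (median -0.72, adjusted p = 0.00258; adjusted p = 0.980 with an estimated correlation). Limma called 0 of 9 over all genes and 3 adjusted over the list alone, 4 had an unadjusted p under 0.05, and the authors' deposited table called 4. Hsd11b2, which inactivates glucocorticoids, stood at 10.6 ± 3.26 and 6.13 ± 1.11 FPKM, and Sgk1 at 98.3 ± 73.2 and 18.0 ± 16.8 FPKM, both chosen after their values were seen.

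Beside these lists, 293 genes outside them were at least 4-fold higher in villi than in crypts in the authors' deposited table of vitamin D treated libraries. These genes had a median log2 fold change of -0.57 in crypts. Since the vitamin D crypt libraries served to pick them, their choice alone can lower this value and the difference below. Their mean per library lay highest in vehicle replicates 6 (1.35) and 5 (1.07) and lowest in vehicle replicate 4 (-1.23). The mean difference after vitamin D was -0.54, which did not pass (exact permutation test, two-sided, p = 0.229, n = 6 and 6; 0.156 by pairs of replicate numbers, 5 of 6 lower). The circadian clock list passed with the replicate number as a block (lower, adjusted p = 0.0155, against 0.159 without it; adjusted p = 0.932 with the block and an estimated correlation). MHC class II genes passed within the plain-named libraries (higher, adjusted p = 0.0033, against 0.117 over all libraries; adjusted p = 0.964 there with an estimated correlation). Other splits of the crypt libraries gave up to 14 called lists.

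**Figure D2:**
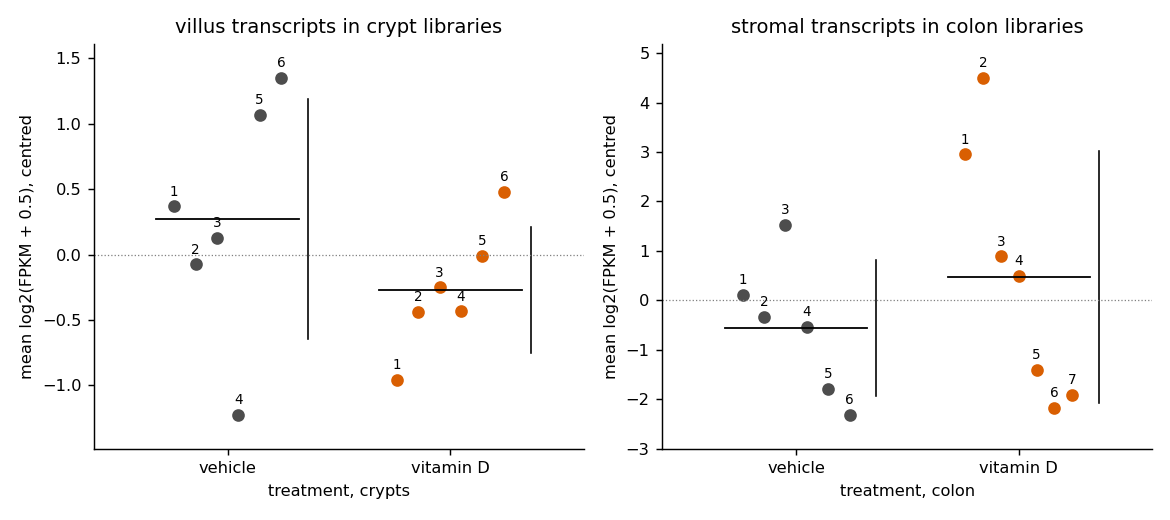
Mean log2 deviation from the mean over libraries of 293 villus genes in each crypt library and of the stromal and smooth muscle list in each colon library, with replicate numbers as points, the mean as a line and the SD as a bar. Vehicle crypt replicate 4 lay at -1.23, and vitamin D colon replicates 1 and 2 at 2.95 and 4.50.

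Slc30a10, Slc30a1 (6.67 to 18.4 FPKM, 1.39 ± 0.13) and Slc39a8 (7.00 to 23.1 FPKM, 1.56 ± 0.29) rose in crypts among 20 genes of zinc, manganese and iron handling, with 3 risen and 2 fallen adjusted over the list alone. The list did not pass (median -0.11, mean 0.13, test higher, adjusted p = 0.517). The RNA-binding protein gene Msi1, a stem cell marker, rose from 6.69 to 14.5 FPKM (1.04 ± 0.19, adjusted p = 0.0131). Of 16 stem cell genes 2 rose and 1 fell adjusted over the list alone, and the list had an adjusted p of 0.517. Median, mean and test also differed in sign for vitamin D receptor and metabolism (-0.02, 0.79, higher, adjusted p = 0.540) and for goblet cells (-0.01, 0.01, higher, 0.517). The same held for tuft cells (0.01, -0.05, lower, 0.978) and for xenobiotic genes (-0.16, 0.02, lower, 0.622). Cd79b was the called member of 9 lymphocyte and plasma cell genes (adjusted p = 0.517 for the list). The lists of phosphate and magnesium, cholesterol synthesis, enteroendocrine cells and pancreatic acinar cells (3 genes measured) had adjusted p of 0.984, 0.882, 0.955 and 0.971.

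In colon, Cyp24a1 rose from 12.8 ± 25.5 FPKM (SD, n = 6) to 2388 ± 992 (n = 7; log2 fold change 9.10 ± 0.88, adjusted p = 0.000274), with vehicle replicate 6 at 64.7 and vitamin D replicate 7 at 403 FPKM. Trpv6 rose from 2.43 ± 2.15 to 29.9 ± 16.4 FPKM (3.53 ± 0.46, adjusted p = 0.00142, and 0.0515 within the plain-named libraries). Atp2b1 rose from 55.2 ± 17.2 to 153 ± 21.4 FPKM (1.50 ± 0.16, adjusted p = 0.000523). S100g stood at 223 ± 144 and 565 ± 244 FPKM (1.42 ± 0.37, adjusted p = 0.131), with 4 of 7 vitamin D libraries above all vehicle libraries. It passed within the plain-named libraries (adjusted p = 0.0162), and in the authors' deposited table its adjusted p was 0.0268. Vdr stood at 179 and 166 FPKM (-0.11 ± 0.15, adjusted p = 0.909). Slc30a10 rose from 11.5 ± 11.2 to 86.3 ± 31.2 FPKM (3.31 ± 0.48, adjusted p = 0.00283) and Prelp from 5.83 to 38.5 FPKM (2.56 ± 0.43, adjusted p = 0.00934).

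Limma called 95 of 11540 genes in colon, of which 88 rose and 7 fell. The fallen count was 1 without vehicle replicate 2, 20 without vitamin D replicate 7, and 2 to 10 without any other library. The class I histocompatibility gene H2-Bl rose by 2.43 ± 0.35, the carbonyl reductase gene Cbr2 by 2.42 ± 0.42, the phosphodiesterase gene Gdpd5 by 2.31 ± 0.33 and Pdlim2 by 1.86 ± 0.25. Cthrc1 (2.16 ± 0.42, adjusted p = 0.0232) and Trim47 (1.91 ± 0.40, adjusted p = 0.0411, and 0.0852 with a pseudocount of 0.1) rose in calls lost without any 1 of 8 and 12 of the 13 libraries, with adjusted p up to 0.103. Cldnd1 fell from 2.17 to 0.294 FPKM (-2.01 ± 0.37, adjusted p = 0.0166, and 0.0593 without vehicle replicate 2), whereas the authors' deposited table gave it an adjusted p of 0.426. Sox13, a transcription factor gene, fell by 0.61 (29.0 to 19.0 FPKM, adjusted p = 0.00779). The hypoxia factor gene Hif1a fell by 0.64 (adjusted p = 0.0291), the sphingomyelinase gene Smpd3 by 0.48 (0.0433), the glutathione synthesis gene Gclc by 0.45 (0.0403) and Sipa1l1 by 0.30 (0.0351). The calls of these 4 were lost without any 1 of 8 to 12 of the 13 libraries, at adjusted p up to 0.127. Within the plain-named libraries, 4 against 4, limma called 78 genes (71 higher, 7 lower), 62 of them among the 95. Pdlim2, Sox13 and these 4 genes did not pass there (adjusted p of 0.0501 to 0.167). The authors' deposited table called 246 genes, 205 higher and 41 lower.

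Calcium absorption was the list of 28 in colon that passed with both correlations (higher, adjusted p = 2.5e-07, and adjusted p = 0.00279 with an estimated correlation). Of its 7 measured members Trpv6 and Atp2b1 rose and 4 rose adjusted over the list alone, with a median of 0.90. The claudin gene Cldn15 stood at 123 ± 24.7 and 237 ± 78.3 FPKM (adjusted p = 0.0593). It was chosen after its values were seen, as were Dhcr7 and Tsc22d3 below. Cholesterol synthesis genes were lower as a list, with 16 of 18 fold changes negative (median -0.27, adjusted p = 0.00798; adjusted p = 0.795 with an estimated correlation). The call was lost without vehicle replicate 3 (0.0561) and within the plain-named libraries (0.0941). Limma called 1 of the 18 over all genes and 2 adjusted over the list alone, all higher. Dhcr7, a reductase of the pathway, stood at 55.7 ± 6.73 and 80.1 ± 12.9 FPKM. Glucocorticoid targets were lower (median -0.49, adjusted p = 0.00242; adjusted p = 0.201 with an estimated correlation), with Tsc22d3 at 18.2 ± 3.31 and 11.7 ± 3.67 FPKM. Limma called 0 of 10 over all genes and 1 adjusted over the list alone, 4 had an unadjusted p under 0.05, and the authors' deposited table called 1.

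Markers of macrophages and granulocytes had positive fold changes in colon in 7 of 7 (median 0.55, adjusted p = 0.0429; adjusted p = 0.795 with an estimated correlation; 0.110 without vehicle replicate 6). Limma called 0 of them, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 in the authors' deposited table. Stromal and smooth muscle markers had 13 of 14 positive fold changes and a median of 1.03 without passing (adjusted p = 0.0582). They passed with name style as a covariate (1.2e-05; adjusted p = 0.707 with an estimated correlation) and within the plain-named libraries (3.5e-06; adjusted p = 0.671 with an estimated correlation). Their mean per library was 2.95 and 4.50 in vitamin D replicates 1 and 2, both plain-named, and at most 1.52 in the others. The difference between the groups in it did not pass (exact permutation test, two-sided, p = 0.398, n = 6 and 7). MHC class II (0.0166), xenobiotic genes (0.00614) and zinc, manganese and iron handling (0.0180) also passed as higher within the plain-named libraries, against adjusted p of 0.228, 0.766 and 0.0822 over all libraries. With an estimated correlation the plain-named libraries gave an adjusted p of 0.844, 0.781 and 0.496. The last list also passed with name style as a covariate (0.0362; adjusted p = 0.577 with an estimated correlation). In it Slc30a10 and Slc39a8 (18.5 to 42.3 FPKM, 1.15 ± 0.18) rose, 3 adjusted over the list alone.

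Median, mean and test differed in sign in colon for vitamin D receptor and metabolism (-0.12, 0.55, lower, adjusted p = 0.366), phosphate and magnesium (-0.01, 0.02, higher, 0.896) and xenobiotic genes (0.02, -0.05, higher, 0.766). Cell cycle genes had 17 of 22 positive and absorptive enterocyte genes 14 of 18 negative fold changes, each with an adjusted p of 0.0582. The enterocyte list passed with name style as a covariate (0.0362; adjusted p = 0.804 with an estimated correlation). The adjusted p of stem cells, Paneth, goblet, enteroendocrine and tuft cells was 0.327, 0.509, 0.854, 0.538 and 0.45. It was 0.366 for fatty acid oxidation and PPAR targets, 0.45 for lymphocytes and plasma cells, 0.395 for endothelium, glia and neurons, and 0.596 for red blood cells. Other splits of the colon libraries gave up to 14 called lists.

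Some lists passed in none of the tissues with the preset correlation over all libraries. Their adjusted p in villi, crypts and colon was 0.899, 0.517 and 0.960 for bile acid handling, 0.899, 0.379 and 0.0582 for tight and adherens junctions, and 0.972, 0.177 and 0.228 for colonocytes. It was 0.577, 0.517 and 0.415 for epithelial antimicrobial defence, 0.339, 0.389 and 0.723 for interferon-stimulated genes, and 0.329, 0.159 and 0.173 for the circadian clock. Immediate early and heat shock genes had 0.432, 0.882 and 0.0512. MHC class II genes had 0.597, 0.117 and 0.228, with 6 of 6, 6 of 6 and 6 of 7 fold changes positive, and 0.0102, 0.0033 and 0.0166 within the plain-named libraries, where an estimated correlation gave an adjusted p of 0.961, 0.964 and 0.844.

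**Figure D3:**
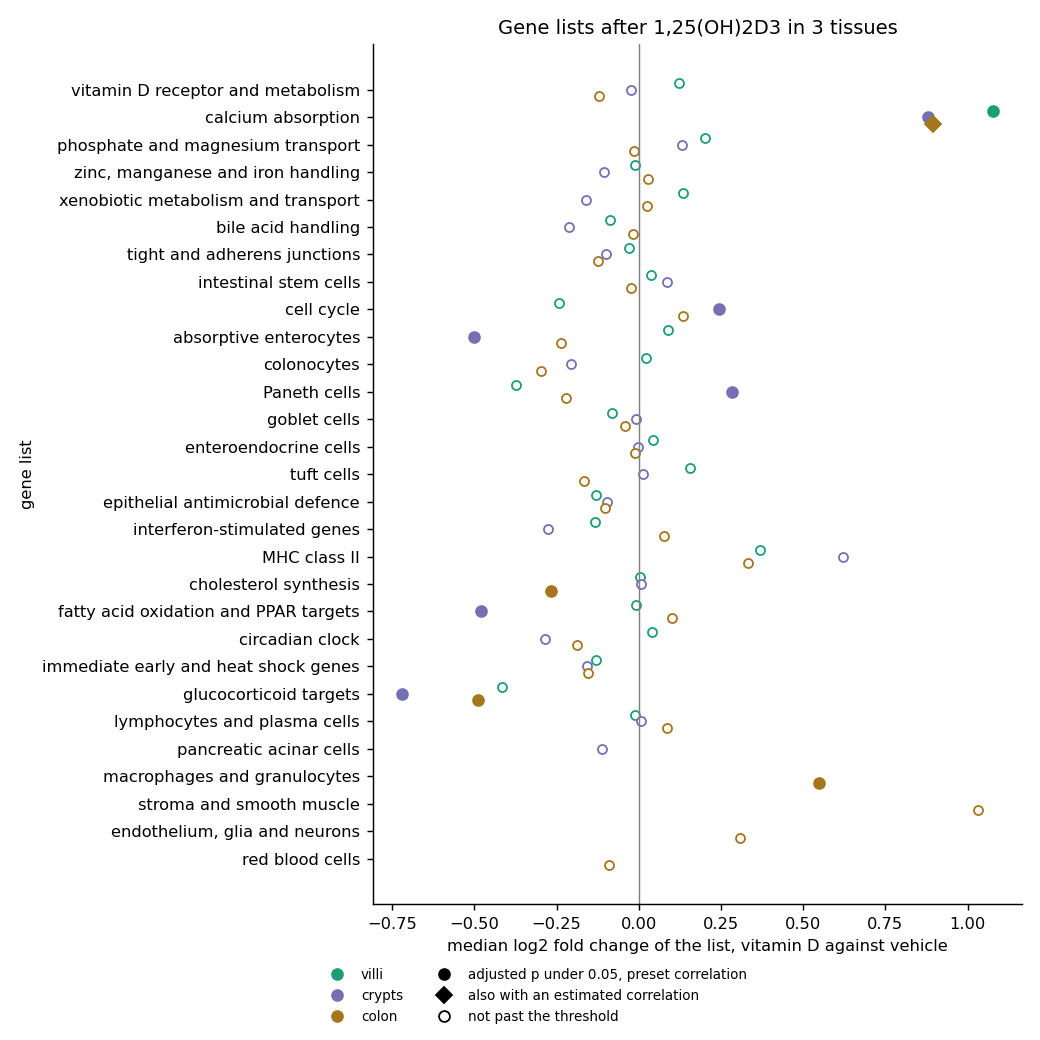
Median log2 fold change, vitamin D against vehicle, of each gene list in villi, crypts and colon, where filled symbols passed camera with the preset correlation and the diamond also with an estimated one. Calcium absorption was filled in each tissue, at medians of 1.08, 0.88 and 0.90.

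The response of 8 of 10942 genes differed between villi and crypts, larger in villi for 2 and in crypts for 6. In these counts, here and below, larger means the higher log2 fold change. A gene that fell in 1 tissue can thus count as larger in the other. Chance could give 8 genes, as 5 of 100 splits of the libraries were as large. These include the real split, and the others had each tissue's response removed and were drawn without regard to replicate numbers. Cnnm1, of a family linked to metal ion transport, stood at 0.412 and 0.615 FPKM in villi and rose from 0.882 to 3.18 FPKM in crypts (difference of log2 fold changes -1.11 ± 0.16, adjusted p = 0.00071). The transcription factor gene Atoh8 (-1.42 ± 0.22), Wfdc16 (-2.38 ± 0.39), 5033404E19Rik (-1.71 ± 0.29) and the secretory kinase gene Fam20c (-1.69 ± 0.29) also changed more in crypts, and the plakin gene Ppl more in villi (1.00 ± 0.18). Genes that passed the filter in either tissue of a pair were tested. Cnnm1, Atoh8, Wfdc16, 5033404E19Rik and Fam20c lay below it in villi, so the added 0.5 weighs on their differences. In villi 5033404E19Rik was listed at 0 in every vehicle library, and its vehicle mean in crypts was 0.0184 FPKM. Atoh8 and Wfdc16 did not pass with a pseudocount of 0.1 (adjusted p = 0.455 and 0.759), and within the plain-named libraries they and Ppl did not (0.324, 0.324 and 0.213). There 5 of the 8 genes passed, and 3 passed with a mean FPKM of at least 5. S100g differed by -2.02 ± 0.55 without passing (adjusted p = 0.393). Cyp24a1 (-0.85 ± 1.17, adjusted p = 0.842), Atp2b1 (-0.23 ± 0.22, 0.792), Trpv6 (-0.17 ± 0.59, 0.948) and Vdr (-0.12 ± 0.25, 0.897) did not pass either. Of genes tested in both tissues, 168 were called in villi and not in crypts, and 2 of these differed, Ppl and, chosen after its values were seen, Zfp961. Of 64 called in crypts and not in villi limma called 0 as different, with 21 at an unadjusted p under 0.05; no other tool was run for the difference.

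Between villi and colon 56 of 11821 genes differed in their response, with the higher log2 fold change in villi for 37 and in colon for 19. Fhl2, a LIM domain gene, stood at 17.6 and 12.2 FPKM in villi and rose from 11.1 to 25.8 FPKM in colon (-1.64 ± 0.22, adjusted p = 8.6e-05). The zinc finger gene Zfp961 (0.79 ± 0.11), the topoisomerase gene Top2b (0.90 ± 0.14) and 5031439G07Rik (1.01 ± 0.14) changed more in villi. Srgap3 (-1.04 ± 0.16), 5033404E19Rik (-1.95 ± 0.28) and Trpv6 (-2.46 ± 0.58, adjusted p = 0.0381) changed more in colon. Of these 3 genes, Srgap3 and 5033404E19Rik lay below the filter in villi. All 3 calls were lost with a pseudocount of 0.1 (adjusted p of 0.0549, 0.389 and 0.356), and that of Trpv6 also within the plain-named libraries (0.224). There 54 genes differed, 26 larger in villi and 28 in colon, 33 of them among the 56. S100g (-0.07 ± 0.54, adjusted p = 0.983), Cyp24a1 (1.42 ± 1.15, 0.737), Atp2b1 (-0.16 ± 0.22, 0.849) and Vdr (0.33 ± 0.24, 0.713) did not pass. Of 190 genes called in villi and not in colon 31 differed, and of 32 called in colon and not in villi 5 did. Slc37a2 and Gstm1 were chosen after their values were seen. The response of Slc37a2 was larger in villi by 2.76 (adjusted p = 0.0376), with 62.3 and 65.8 FPKM in colon, and that of Gstm1 by 2.26 (adjusted p = 0.0177).

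Between crypts and colon 19 of 11895 genes differed, with the higher log2 fold change in crypts for 11 and in colon for 8. Of 100 splits of the libraries 4 gave as large a count, so chance is not excluded. These include the real split, and the others had each tissue's response removed. Cnnm1 rose in crypts and stood at 1.53 and 1.09 FPKM in colon (1.77 ± 0.16, adjusted p = 8.9e-09). Pgap1, of lipid anchor remodelling, rose from 4.61 to 11.9 FPKM in crypts against 5.02 and 4.52 in colon (1.38 ± 0.26, adjusted p = 0.0074). Pip5k1b also changed more in crypts (0.57 ± 0.10), and Srgap3 (-1.05 ± 0.16), A830010M20Rik (-1.33 ± 0.21) and the prostaglandin E synthase gene Ptges (-1.39 ± 0.26) more in colon. Srgap3, A830010M20Rik and Ptges lay below the filter in crypts. Of these, Srgap3 and Ptges did not pass with a pseudocount of 0.1 (adjusted p = 0.0961 and 0.0938), where 10 genes passed, 8 larger in crypts and 2 in colon. Nor did Pip5k1b within the plain-named libraries (0.107), where 13 passed, 4 larger in crypts and 9 in colon, 8 of them among the 19. S100g differed by 1.95 ± 0.55 (adjusted p = 0.279) and Trpv6 by -2.29 ± 0.59 (adjusted p = 0.181, and 0.0150 with a pseudocount of 1). Cyp24a1, Atp2b1 and Vdr had adjusted p of 0.995, 0.999 and 0.995. Of 111 genes called in crypts and not in colon 7 differed, and of 47 called in colon and not in crypts 1 did, Dcxr. Slc30a1, chosen like Dcxr after its values were seen, changed more in crypts (1.06, adjusted p = 0.0288) and in villi (1.05, adjusted p = 0.0142) than in colon.

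Genes called in several tissues shared their direction, with 0 of the 9311 genes tested in each tissue called in opposite directions in any pair. Of these genes 25 rose in all 3 tissues, among them Cyp24a1, Slc30a10, Atp2b1, Slc39a8, Gdpd5 and Ptprj, and 0 fell in all 3. Villi and crypts shared 61 risen genes where independent lists would share 2.12 (Fisher's exact test, two-sided, p = 1.1e-79) and 5 fallen genes against 0.0977 (p = 3.5e-08). The 5 were Adh4, Arl4d, Lrat, the sphingosine kinase gene Sphk1 and the interferon gamma receptor gene Ifngr1, the last 2 chosen after their values were seen. Villi and colon shared 43 risen genes against 1.56 (exact p = 1.4e-54) and 1 fallen gene, Sox13, against 0.0143 (exact p = 0.0142). Crypts and colon shared 33 risen genes against 0.799 (exact p = 5.7e-47) and 0 fallen genes against 0.0185 (exact p = 1). Whether a mouse gave several of the tissues is not given in the sources used here, and the tests of overlap take no account of it. The number prefixes of villus and colon libraries are consecutive, which does not settle it. With treatment and title number as a block across tissues, 9, 84 and 21 genes differed in response, in the order of pairs above. These held all 8, 56 and 19 genes found without the block (correlation within blocks 0.117, 0.111 and 0.111). Some libraries joined by this block differed in sex pattern.

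**Figure D4:**
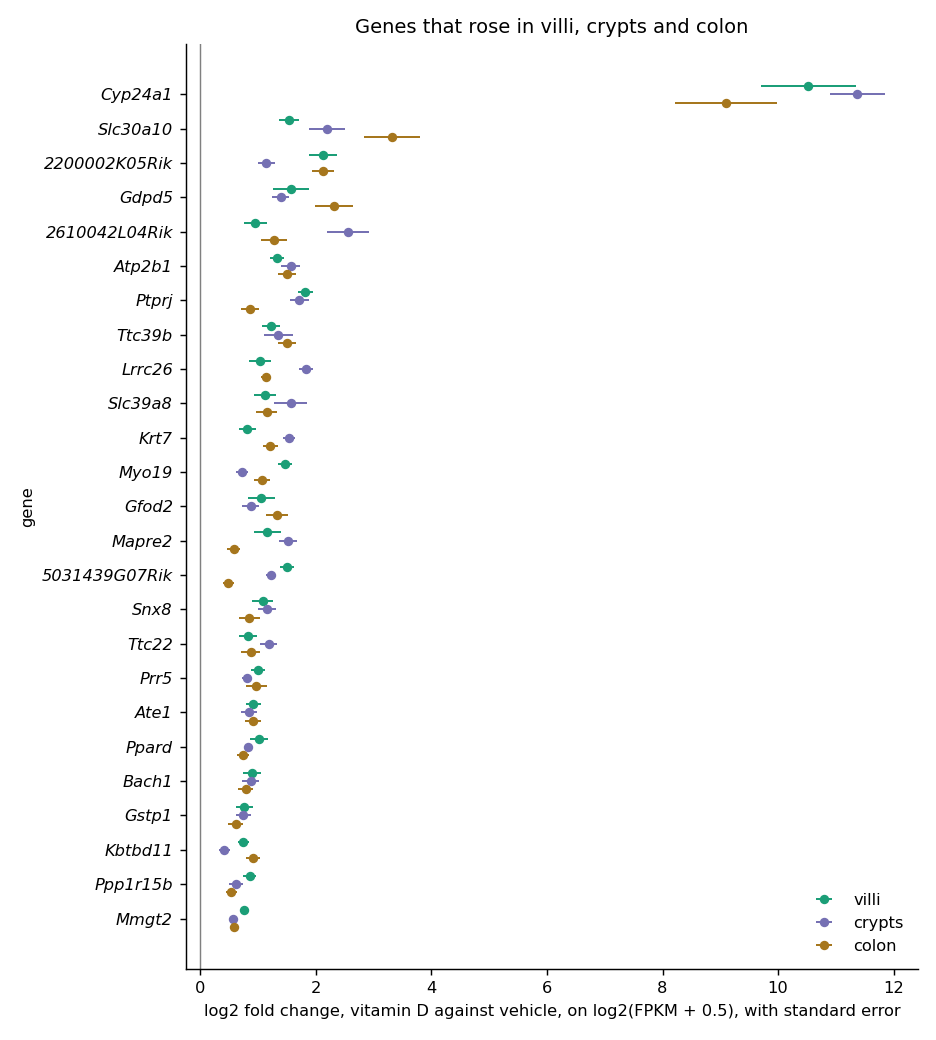
Log2 fold changes on log2(FPKM + 0.5), with their standard errors, of the 25 genes that rose in villi, crypts and colon. Cyp24a1 lay between 9.10 and 11.37, and Slc30a10 at 1.53, 2.19 and 3.31.

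Crypts differed from villi among vitamin D treated libraries in 9391 of 15162 genes of the authors' deposited table, higher in crypts for 4785. By the authors' deposited table, 13 of 13 Paneth cell genes and 22 of 22 cell cycle genes were higher in crypts, such as the defensin gene Defa21 (log2 fold change 5.35), the mitotic kinase gene Aurkb (4.13) and Mcm3 (4.06). So were 15 of 18 stem cell genes in the authors' deposited table, with Ascl2 at 4.24 and Tnfrsf19 at 4.35. The authors' deposited table had 20 of 20 absorptive enterocyte genes lower in crypts, among them the peptide carrier gene Slc15a1 (-2.90) and the apolipoprotein gene Apoa4 (-2.81). In the authors' deposited table, 19 of 23 xenobiotic and 14 of 17 interferon-stimulated genes were also lower in crypts. Among mineral transport genes the authors' deposited table had Cldn2 (1.52), the transferrin receptor gene Tfrc (2.38) and Slc39a8 (1.51) higher in crypts. Atp2b1 (-0.80), Slc34a2 (-4.37) and the ferroxidase gene Heph (-1.81) were lower in crypts in the authors' deposited table.

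Colon differed from villi in 10797 of 16681 genes of the authors' deposited table, higher in colon for 6299. The authors' deposited table had 20 of 20 enterocyte genes lower in colon than in villi, including the glucose carrier gene Slc2a2 (-9.05) and the lactase gene Lct (-9.04). It had 11 of 13 colonocyte genes higher, including the sodium channel genes Scnn1g (8.93) and Scnn1b (8.92) in the authors' deposited table. S100g (-2.34) and Cldn15 (-1.97) were lower in colon than in villi and Slc39a8 (2.18) higher in the authors' deposited table. Among xenobiotic enzyme genes, Cyp3a11 (-9.72) and Cyp2b10 (-9.12) were lower and Cyp2c55 (4.19) higher in colon in the authors' deposited table.

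Colon differed from crypts in 9425 of 16667 genes of the authors' deposited table, higher in colon for 5435. The authors' deposited table had Trpv6 (4.41), the carbonic anhydrase gene Car1 (12.29) and the bile acid carrier gene Slc10a2 (6.59) higher in colon than in crypts, and S100g (-2.22) lower. In the authors' deposited table, 13 of 13 Paneth cell genes, such as Defa5 (-10.50), and 20 of 22 cell cycle genes were lower in colon than in crypts. All 15 stromal and smooth muscle genes were higher in colon than in villi and in crypts in the authors' deposited table, with the highest means of this list in vitamin D colon replicates 1 and 2.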

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

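The tests of exchanged or mixed libraries, of the difference in villus and stromal genes between the groups, and of independent muscle genes were chosen only after the result was seen. For the fits with villus or stromal genes as a covariate, what they would show was set down before their results were seen. Those fits were not among the tests fixed before the data were examined, and they address patterns seen in the data.

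Cyp24a1 lay between the groups in 4 libraries, at 62.2 FPKM in vehicle villi replicate 6, 7.35 in vehicle crypts replicate 5, 64.7 in vehicle colon replicate 6 and 403 in vitamin D colon replicate 7. An exchange of libraries between the groups is excluded: over 60 other raised genes, set to 0 for vehicle and 1 for vitamin D, the 3 vehicle libraries reached at most 0.296 and every vitamin D library at least 0.547. A uniform mix with vehicle material as the whole cause is argued against in vitamin D colon replicate 7, since these genes stood at a median of 37.1% of the treated level (middle quartiles 17.3% to 69.9%) and Cyp24a1 at 14.4%. As the source of Cyp24a1 in the 3 vehicle libraries, a trace of treated material cannot be told apart from a response of these samples. Cyp24a1 asks for 1.82%, 0.190% and 2.61%, and the other genes stood at 3.37%, 2.26% and 22.4% of the treated level. Other vehicle libraries of villi, crypts and colon spread from -5.17% to 11.6%, -4.56% to 10.8% and -5.67% to 8.33%. In vehicle colon replicate 6 a trace of 2.61% would not by itself give the values of the other genes (middle quartiles 4.29% to 37.2%). A partial delivery of the hormone to vitamin D colon replicate 7 may account for its values but was not tested.

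In vitamin D crypts 293 villus genes had a median log2 fold change of -0.57, and the cell cycle (median 0.24) and Paneth cell (0.28) lists passed as higher with 0 of 22 and 0 of 13 genes called by limma (7 and 0 at an unadjusted p under 0.05, 0 and 0 in the authors' deposited table), but not with an estimated correlation (adjusted p = 0.980 each), and the stem cell list did not pass (0.517). The villus genes were picked with the vitamin D crypt libraries themselves, which alone can lower their median. Villus material as the cause of most of the 157 called genes is argued against. With the mean of the villus genes that were not called as a covariate, the fold changes kept a median of 0.949 of their size (middle quartiles 0.868 to 1.02). Of the 157 genes 151 remained called. The fallen genes, which less villus material would lower, were not set apart, so it is not excluded for each gene. Less villus material in the vitamin D crypts might account for the lower enterocyte genes, but the difference in the villus genes did not pass (exact permutation test, p = 0.229 over 924 regroupings; 0.156 by pairs of replicate numbers, where 5 of 6 were lower and replicate 4 was higher by 0.79). A change in crypt cells would give the same values, and these 2 explanations cannot be told apart with 6 libraries per group. The lower enterocyte list rested on vehicle crypts replicate 6, without which its adjusted p was 0.192.

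Smooth muscle and stromal transcripts were high in vitamin D colon replicates 1 and 2, with list means of 2.95 and 4.50. Muscle wall in the scraped epithelium is a candidate explanation that cannot be told apart from a change in the tissue itself: 8 muscle genes outside the list, which restate the pattern since they were picked once muscle genes had been seen high, exceeded the other libraries by a median log2 value of 4.31 in replicate 1 and 5.33 in replicate 2, with Myl9 at 903 and 2779 FPKM against a mean of 21.6. Stromal material as the cause of most of the 95 called genes is argued against. With the stromal mean as a covariate their fold changes kept a median of 0.995 of their size (middle quartiles 0.951 to 1.03), and 85 remained called. It is not excluded for each gene. The treatment as the cause stays open too, as the difference between the groups in the stromal mean did not pass (exact permutation test, p = 0.398 over 1716 regroupings).

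Among 209 groups of libraries of named genes, 18 held a library far from the others by Dixon's test, where chance marks about 1 in 20 groups, and 3 of these are the Cyp24a1 values given above for villi, crypts and vitamin D colon replicate 7. In vitamin D colon replicate 7, Cbr2 (18.9 FPKM), Gdpd5 (2.91) and Cnnm1 (1.57) also stood apart from the other vitamin D colon libraries. Cldnd1 stood apart in vitamin D colon replicate 6 (2.03 FPKM), Smpd3 in vitamin D colon replicate 2 (21.2), Trim47 in vehicle colon replicate 6 (0.0) and Vdr in vehicle colon replicate 1 (118). In crypts these were 5033404E19Rik in vehicle replicate 4 (0.110 FPKM), Trpv6 in vehicle replicate 3 (0.809), Fam73b in vitamin D replicate 6 (1.78) and Srgap3 in vitamin D replicate 4 (0.351). In villi they were Ptprj (4.60 FPKM) and Srgap3 (0.156) in vehicle replicate 3, Tubb2a in vehicle replicate 6 (12.2) and Slc37a2 in vitamin D replicate 5 (63.6).

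The genes that follow passed the test of a difference in response between tissues, each value being a difference of log2 fold changes. Those that lay below the filter in 1 tissue are named in the results. For villi minus crypts these were Cnnm1 (-1.11), Atoh8 (-1.42), Wfdc16 (-2.38), 5033404E19Rik (-1.71), Fam20c (-1.69) and Ppl (1.00), of 8 genes. That count was reached by 5 of 100 splits of the libraries, so that chance cannot be excluded. The 5 include the real split, and the others had each tissue's response removed. For villi minus colon they were Fhl2 (-1.64), 5031439G07Rik (1.01), Zfp961 (0.79), 5033404E19Rik (-1.95), Top2b (0.90), Srgap3 (-1.04) and Trpv6 (-2.46). For crypts minus colon they were Cnnm1 (1.77), Srgap3 (-1.05), A830010M20Rik (-1.33), Pip5k1b (0.57), Ptges (-1.39) and Pgap1 (1.38). These were among 19 genes, a count that 4 of 100 splits of the libraries reached, the real one included and the others with each tissue's response removed.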

How the results depend on the processing

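Fits with sex as a covariate, without 1 library, with the plain-named libraries alone for lists and differences, within the other name styles and with the block by column names were chosen only after the results were seen. No called gene or list was reversed by an alternative setting, and of the named genes' values over the settings with all or only the plain-named libraries, a covariate or the block by titles, and in the authors' deposited tables, 941 kept their side of the threshold, 55 lost and 6 gained a call; for lists these were 420, 15 and 27. Without 1 library 17 of 64 called values of named genes lost the call in at least 1 fit (122 of 811 fits), as did 5 of 11 called lists, and 19 other lists gained one. The settings that moved a count by over 1.5 times follow, and the cause was not tested except where fewer libraries or a fold threshold lower a count by construction. With an absolute log2 fold change of at least 1 the counts of called genes in villi, crypts and colon were 64, 59 and 51. They were 436, 550 and 246 in the authors' deposited tables, and with plain-named libraries only 97 in villi and 84 in crypts. With 2 against 2 libraries limma called 0 genes within the number prefix in villi and 0 in colon (1618 and 226 at an unadjusted p under 0.05). It called 1 within the hyphen in crypts, and no other tool was run for these fits. All of the 240, 95 and 157 called genes kept their sign, but these same libraries had helped to pick them, so this is no independent check. Array weights gave 1253 in crypts and 176 in colon, the replicate block 444 in crypts and 147 in colon, where the numbers did not pair the libraries (3 of 6 pairs correlated over 0.1, or 4 of 6 by the column names, and 2 of 6 vehicle libraries best with their own number), name style as a covariate 391 and sex as a covariate 272 in crypts. The replicate block by column names gave 354 genes in villi, with Bid no longer called (adjusted p = 0.0540), and 81 in colon. Beyond the calls named in the report the block by titles changed no other call of a named gene or list in villi or crypts. Called lists numbered 0, 0 and 1 in villi, crypts and colon with an estimated correlation, 3 in villi and 7 in colon with name style, 3 and 9 with the replicate block, 3 and 7 with plain-named libraries only, and 4 in villi with sex as a covariate. Differing genes numbered 3 between villi and crypts with a mean FPKM of 5 or more and 5 with plain-named libraries only, and 10 between crypts and colon with a pseudocount of 0.1. At an adjusted p below 0.01 the shared risen genes numbered 30 in villi and crypts, 20 in villi and colon and 21 in crypts and colon, and the shared fallen genes 1, 0 and 0, with fewer genes called in each tissue. At an absolute log2 fold change of 1 the tissue tables gave 5057, 6835 and 5180 genes for crypts against villi, colon against villi and colon against crypts. Without 1 library the called genes numbered 176 to 223 in villi, 107 to 1065 in crypts (highest without vehicle replicate 4) and 66 to 141 in colon (highest without vitamin D replicate 7), with 15 to 28, 18 to 449 and 1 to 20 fallen genes, and called lists 1 to 7, 4 to 8 and 3 to 9. Between 24.2% and 34.2% of genes were at 0 in a library.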

Other observations

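The genes of the first 2 paragraphs and the list means of colon were chosen, and the tests by splits of the libraries and what they would show were set down, only after the results were seen. Orai1, a subunit of the store-operated calcium channel, rose in villi from 20.3 ± 6.20 FPKM (SD, n = 6) to 54.5 ± 13.7 (n = 7; log2 fold change 1.42 ± 0.20, adjusted p = 0.000892) and in crypts from 17.8 ± 2.23 to 44.8 ± 6.65 FPKM (1.30 ± 0.11, adjusted p = 5.9e-05). In colon it did not pass (0.51 ± 0.14, adjusted p = 0.137). Soat1, which esterifies cholesterol, rose by 1.46 ± 0.20 in villi and 1.66 ± 0.20 in crypts, against 0.39 ± 0.17 in colon (adjusted p = 0.543). The nuclear receptor gene Ppard rose in each tissue, by 1.01 ± 0.15 in villi, 0.83 ± 0.07 in crypts and 0.73 ± 0.10 in colon, and Bach1, a repressor of haem oxygenase, by 0.89, 0.87 and 0.78.

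Of the class I histocompatibility genes, which were not tested as a group, H2-Q1 rose in colon from 48.9 ± 21.4 to 134 ± 20.3 FPKM (1.54 ± 0.22, adjusted p = 0.00269) and H2-Q2 by 1.29 ± 0.20 (adjusted p = 0.00423). In villi H2-Q1 rose by 0.48 ± 0.11 (adjusted p = 0.0358) and H2-Q2 did not pass (0.0967), and in crypts neither passed (0.478 and 0.567). Ifngr1, the interferon gamma receptor gene, fell from 68.3 ± 7.38 to 43.5 ± 4.47 FPKM in villi (-0.64 ± 0.09, adjusted p = 0.0011) and from 79.6 ± 9.82 to 51.2 ± 3.15 FPKM in crypts (-0.62 ± 0.09, adjusted p = 0.00254). In colon it did not pass (-0.45 ± 0.17, adjusted p = 0.45). Sphk1, which makes sphingosine 1-phosphate, fell in villi (adjusted p = 0.0295) and crypts (0.0137). In crypts Phgdh, of serine synthesis, rose by 1.63 (adjusted p = 0.0054), the urea transporter gene Slc14a1 by 1.68 (0.0321) and Pparg by 0.94 (0.0206).

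In colon the 4 libraries with a number prefix in their name, all male, had the highest mean of the absorptive enterocyte list, at 2.23 and 1.53 in vehicle replicates 5 and 6 and 1.14 and 1.01 in vitamin D replicates 6 and 7, against -0.35 or less in the others. Vehicle colon replicate 5 also had the highest mean of the Paneth cell list, 4.62.

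Of 100 splits of the libraries into groups of the real sizes, the real one included, 1 gave as many called genes in villi as the real 240 (highest other 5). In crypts 2 gave as many as the real 157 (highest other 839), and in colon 1 as many as the real 95 (highest other 16). Chance is argued against for the counts in villi and colon. In crypts a drawn split exceeded the real count, so these splits do not exclude chance there. For the differences between tissues these splits, with 3, 1 and 4 as large for villi and crypts (8 genes, highest other 91), villi and colon (56, highest other 32) and crypts and colon (19, highest other 979), also take away the response itself and so do not test equal responses. With each tissue's response removed first from all but the real split, which is again included, 1 of 100 splits was as large for villi and colon (highest other 52). For crypts and colon 4 of 100 were (highest other 243), and for villi and crypts 5 of 100 (highest other 302). These splits were drawn without regard to replicate numbers, and no correction was made for testing several pairs of tissues. The values argue against chance for villi and colon, where the highest other count lay near the real 56. For the other pairs chance is not excluded. The splits say nothing on the overlaps (66, 44 and 33 genes, 1 split each, highest other 0), since none of the others called genes in both tissues of a pair. Chance cannot be excluded for the number of called lists, which 99 splits in villi (real 1, highest other 11), 69 in crypts (real 6, highest other 14) and 95 in colon (real 4, highest other 14) reached. The split of the crypts with 839 calls points to a structure of the samples, which was not resolved: it put the 4 libraries with a hyphen in their name on 1 side and both male libraries on the other, and the mean of the villus genes was -0.08 to 1.35 on the first side and -1.23 to 0.13 on the second. With name style as a covariate 391 genes were called in crypts, and 84 within the plain-named libraries. Among splits that part all 6 replicate pairs, the real one gave the most calls in villi (240 genes, 64 splits, highest other 138, where all 6 numbers are exchanged) and in crypts (157 genes, 32 splits, highest other 0).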
